A study of Mus musculus with 27 samples.

How the data were processed

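Polyadenylated RNA of mouse embryonic stem cells was sequenced in 4 libraries, and these are the measurements analysed. The cells were of the KH2 line, a mouse embryonic stem cell line made for doxycycline-inducible transgenes, and carried tagged histone H3 genes. They were kept in medium with LIF and the 2 kinase inhibitors of the naive state (a MEK inhibitor at 1 µM and a GSK3 inhibitor at 3 µM), synchronised by a double thymidine block and released into S phase. The other 23 of the 27 samples in the series are chromatin immunoprecipitation or input libraries, and they are not analysed here.

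The deposited values are per transcript. Per the file headers, each library has a transcript name, a length, an effective length, a TPM value and an estimated count of reads, the columns that the Salmon quantifier writes; its version, the transcript set and the library type are not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.4, Bowtie 1.0.0 and SAMtools 1.0.6 were used and the builds were mm10 and dm3, with the same list for every sample and no role stated for the RNA libraries. The deposited estimated counts are not normalized, and need not be whole numbers, since an estimator of this kind splits reads that fit several transcripts among them. The deposited TPM values divide these estimated counts by effective length and are scaled to the same sum in every library. In the 4 libraries, effective length was a constant distance below length for 99.2% of transcripts of 2000 to 9000 nt, within 0.02 nt.

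All 4 libraries list the same 137271 transcripts. None of the identifiers (0 of 137271) occurs in the gene tables used here, so transcripts were not summed per gene and genes are not named. The count test planned before the data were examined was a ratio per gene; it was run per transcript instead. The 36 gene lists, the scaling to ribosomal protein genes, the total without mitochondrially encoded genes, the read shares of transcript classes and the conditions on gene symbols needed gene names and were not run. The rule planned for named genes would have given up to 10 genes in each direction for 3 comparisons. Its ranking was applied to the triptolide comparison at 6 h alone: at least 100 reads in the higher library, the same direction under all 3 scalings, ranked by the bound of the counting interval nearest to no change. The first 4 transcripts by that ranking all had estimates that were not whole and all were at 0 in 1 of the 6 h libraries, and 2 of them had the opposite ratio at 3 h. The ranking was therefore limited to transcripts with whole-number estimates, a restriction added after the values were seen, and 2 transcripts in each direction are given.

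Estimated counts were rounded to whole reads and expressed as CPM, reads per 1000000 reads of the library. Transcripts with a mean CPM of 1 or more over the 4 libraries were tested (32199 transcripts, 98.4% to 98.6% of the reads). Log2 ratios of CPM were formed for 4 pairs of libraries, and a count of 0 was set to 3 reads, so that such a ratio is a lower bound in size. The rule for a difference was one of size, at least 2-fold. Each group has 1 library, so no ratio has a replicate check and no p-value is given. The 95% intervals of single ratios are exact conditional binomial (Clopper-Pearson) intervals, those of medians over transcripts are binomial order-statistic intervals, and those of shares are Clopper-Pearson intervals. The difference of the 6 h and 3 h log2 ratios has an interval from a normal approximation of the 4 counts. All of them cover counting error or the spread over transcripts only: reads without molecular identifiers are not independent molecules, transcripts are not replicates, and the division of shared reads among transcripts adds error that none of them contains. As a gauge of that error, 317 tested transcripts had estimated counts that were whole in all 4 libraries within 1e-06, as happens when no read is shared; they are called whole-number transcripts.

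Library totals were 27443889 reads (untreated, 3 h), 27242760 (triptolide, 3 h), 24913767 (untreated, 6 h) and 19145129 (triptolide, 6 h). A count of 0 allows up to 3 reads, or 0.109, 0.110, 0.120 and 0.157 CPM in that order. The procedure was tested on simulated Poisson counts at the real abundances and totals. In the simulated triptolide comparison at 6 h, 99 of 100 transcripts changed 4-fold and 98 of 100 changed 3-fold were called. With none of 32243 simulated transcripts changed, counting noise alone gave 60 transcripts at least 2-fold lower and 37 higher in that comparison.

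Alternatives tried were TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, no filter on mean CPM (10 reads summed over the libraries compared), a mean CPM of 5 or more, log2(TPM + 0.1), thinning to the smallest total, limits of 1.5-fold and 4-fold, and intervals wholly beyond 2-fold. The restriction to whole-number transcripts and a mean CPM of 10 or more were chosen after the data were seen, as were the length and abundance classes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.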

Results

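The 4 RNA libraries came from synchronised mouse embryonic stem cells at 3 h and 6 h after release into S phase, each time without and with 1 µM triptolide. Triptolide is a plant diterpenoid that binds XPB, the helicase subunit of the general transcription factor TFIIH, and blocks initiation by RNA polymerase II. The labels do not say when the drug was added. The series concerns where parental nucleosomes go when active and repressed domains are replicated, and the labels give no separate purpose for the RNA libraries. Each condition had 1 library, so every difference compares 2 libraries and has no replicate check. Totals ran from 19145129 reads (triptolide, 6 h) to 27443889 (untreated, 3 h).

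A few abundant transcripts held a larger share of the reads in the treated libraries. The 10 highest transcripts took 11.7% of reads in the untreated and 13.7% in the triptolide library at 3 h, and 11.4% and 14.7% at 6 h. As shares of TPM these were 26.1% and 28.4% at 3 h, and 25.4% and 28.7% at 6 h. The exact binomial intervals of these shares, which cover counting error only, were about as narrow as the last digit printed; those of the untreated libraries did not overlap each other either, so they do not bear on the treatment. Of the 10 highest transcripts, 8 were shared by all 4 libraries. Transcripts at 1 CPM or more numbered 31904 untreated and 31272 treated at 3 h, and 32641 and 30529 at 6 h. The treated 6 h library was also the shallowest.

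With triptolide at 3 h, most transcripts held a share of the reads close to that in the untreated library, and more were lower than higher. All scalings used here compare shares within a library, and no spike-in values were used. A fall common to all transcripts would therefore not be seen, at 3 h or at 6 h, and the counts of lower transcripts are relative. Of 32199 transcripts tested, 2562 (7.96%) were at least 2-fold lower and 1732 (5.38%) at least 2-fold higher. Simulated counting noise gave 19 and 24, but these simulations hold neither the splitting of reads nor differences between libraries. The untreated pair of libraries, 6 h against 3 h, gave 1240 lower and 1390 higher. The median log2 ratio with triptolide at 3 h was -0.04 (95% interval -0.05 to -0.03). It changed sign, to 0.0043 and 0.0050, with TMM factors and DESeq2 size factors, and moved the other way, to -0.12, in TPM. With library totals it was 0.03 (interval 0.02 to 0.05) at a mean CPM of 100 or more, the opposite sign, and -0.01 (interval -0.13 to 0.03) among whole-number transcripts. Among the 10926 transcripts with a mean CPM of 10 or more, 334 (3.06%) were at least 2-fold lower and 142 (1.30%) higher. Among the 1596 with a mean CPM of 100 or more, 20 (1.25%) were lower and 8 (0.501%) higher. Most transcripts past 2-fold at 3 h thus had a mean CPM under 10. Of the 317 whole-number transcripts, whose estimated counts were whole in all 4 libraries, 15 (4.73%) were lower and 5 (1.58%) higher.

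With triptolide at 6 h, the lower group was larger. At least 2-fold lower were 7955 of 32199 transcripts (24.7%), and 3435 (10.7%) were at least 2-fold higher. Simulated counting noise gave 60 and 37, and the untreated pair, 6 h against 3 h, gave 1240 and 1390. With triptolide at 6 h, 2698 were at least 4-fold lower and 1074 at least 4-fold higher. The median log2 ratio was -0.23 (95% interval -0.24 to -0.21), and the spread between the 25th and 75th percentiles was 1.39, against 0.70 at 3 h. The median was -0.10 (interval -0.29 to 0.08) among whole-number transcripts and 0.03 (interval -0.01 to 0.07) at a mean CPM of 100 or more, and both intervals included 0. Among transcripts with a mean CPM of 10 or more, 2322 (21.3%) were lower and 420 (3.84%) higher. Among those with a mean CPM of 100 or more, 174 (10.9%) were lower and 35 (2.19%) higher. Of the whole-number transcripts, 71 of 317 (22.4%, interval 17.9% to 27.4%) were lower and 27 (8.52%, interval 5.69% to 12.2%) higher. Scaling with TMM factors raised every 6 h log2 ratio by 0.22 and DESeq2 size factors raised it by 0.23, which brought the median to -0.01 and, with a change of sign, to 0.0028. The lower transcripts made up 69.8% of those past 2-fold with library totals, 58.2% with TMM, 57.4% with size factors and 81.9% in TPM, so they were the larger group under each of the 4. In TPM the counts were 9753 lower and 2153 (6.69%) higher, the higher count being less by over 1.5 times.

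**Figure D1:**
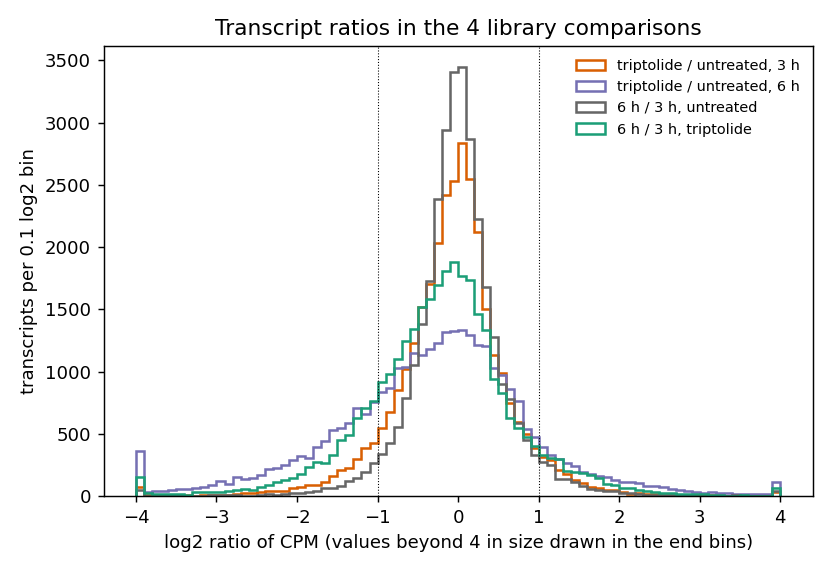
Distribution of log2 CPM ratios of 32199 transcripts in the 4 pairs of libraries; the horizontal axis is the log2 ratio, the vertical axis the number of transcripts per bin, and dotted lines mark 2-fold. The triptolide ratios at 6 h are the widest and reach furthest to the left (7955 at least 2-fold lower), and the untreated 6 h against 3 h ratios are the narrowest (1240 lower).

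Transcripts are given by identifier because no gene names were used. The restriction to whole-number estimates, within which the transcripts named here ranked first at 6 h, was added after the values were seen. The transcript ENSMUST00000060427.4 (1522 nt) had 98.5 CPM in both untreated libraries, 22.7 CPM with triptolide at 3 h and 12.5 CPM at 6 h. It was 4.34-fold lower at 3 h and 7.86-fold lower at 6 h (log2 ratio -2.97, counting interval -3.17 to -2.78). ENSMUST00000052140.2 (2810 nt) was at 49.2 and 42.3 CPM untreated and at 24.9 and 7.94 CPM treated at 3 h and 6 h, 5.33-fold lower at 6 h (log2 ratio -2.42, interval -2.67 to -2.17). ENSMUST00000049699.8 (3255 nt) was higher with the drug, at 41.8 against 23.2 CPM at 3 h and 41.0 against 15.0 CPM at 6 h, a log2 ratio of 1.45 at 6 h (interval 1.27 to 1.64). ENSMUST00000039044.1 (1703 nt) rested on few reads. It had 2 and 6 reads untreated, and 17 and 119 reads with triptolide, at 3 h and 6 h; its log2 ratio at 6 h was 4.69 with an interval of 3.53 to 6.16. Whole-number estimates and the same direction under all 3 scalings were conditions of the choice, so they lend these 4 no support. All 4 also had the same direction at both times. That was not a condition, but the restriction was added after 2 of the first 4 transcripts ranked without it had shown the opposite ratio at 3 h.

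Whether the same transcripts differed at both times was examined across transcripts, which are not independent replicates; the 2 triptolide ratios share no library. Of the 2562 transcripts at least 2-fold lower at 3 h, 1650 (64.4%) were also at least 2-fold lower at 6 h, where independent lists would share 633, and 150 were at least 2-fold higher. Of the 1732 at least 2-fold higher at 3 h, 823 (47.5%) were also higher at 6 h, where independent lists would share 185, and 177 were lower. The log2 ratios at 3 h and 6 h correlated across all tested transcripts with a Pearson r of 0.46 and a Spearman rho of 0.51. The values were 0.65 and 0.70 at a mean CPM of 10 or more, and 0.77 and 0.72 among the whole-number transcripts. The 6 h log2 ratio was lower than the 3 h ratio by 1 or more in 6332 transcripts and higher by 1 or more in 3008, against 231 and 239 from simulated counting noise. The median difference was -0.20 (95% interval -0.21 to -0.18). It was -0.02 with TMM, -0.01 with size factors and -0.37 in TPM. With library totals it was -0.20 at a mean CPM of 10 or more, -0.05 (interval -0.16 to 0.03) among whole-number transcripts and -0.0272 (interval -0.0534 to -0.0023) at a mean CPM of 100 or more. The lower median at 6 h thus depends on the scaling and on the transcripts taken. Of the transcripts whose difference was 1 or more in size, the lower ones made up 67.8% with library totals, 56.2% with TMM, 55.7% with size factors and 77.9% in TPM.

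**Figure D2:**
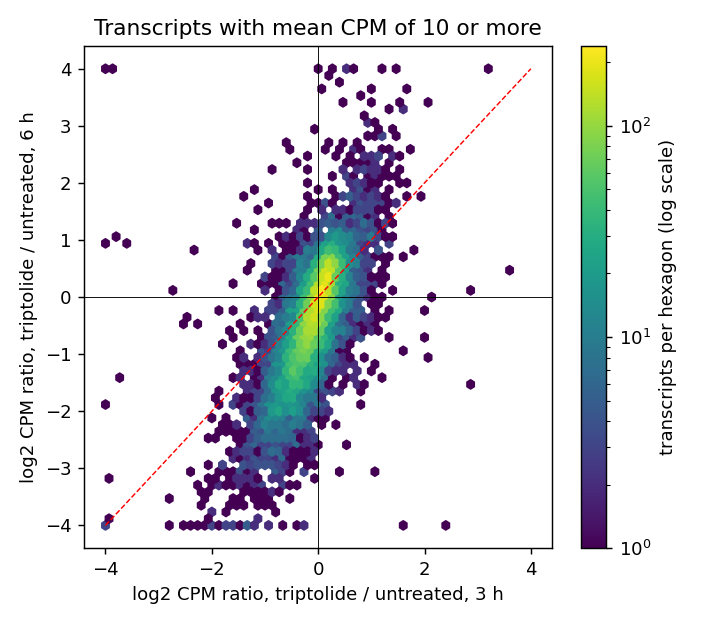
Log2 CPM ratio of triptolide over untreated at 3 h (horizontal) and at 6 h (vertical) for 10926 transcripts with a mean CPM of 10 or more, as counts per hexagon on a log colour scale; the dashed line marks equal ratios and values beyond 4 are drawn at the edge. The cloud runs from lower left to upper right (Pearson r 0.65), and 2322 transcripts lie at least 2-fold below the untreated level at 6 h against 334 at 3 h.

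The time comparisons asked how far expression moved between 3 h and 6 h. Without triptolide the libraries lay close together: 1240 transcripts (3.85%) were at least 2-fold lower at 6 h and 1390 (4.32%) higher. The median log2 ratio was -0.0041 over all tested transcripts (interval -0.0089 to 0.0006). The median was -0.12 (interval -0.17 to -0.10) among whole-number transcripts and 0.02 (interval 0.01 to 0.03) at a mean CPM of 100 or more. At a mean CPM of 10 or more, 62 of 10926 transcripts were at least 2-fold lower and 68 higher. With triptolide, 5503 transcripts (17.1%) were at least 2-fold lower at 6 h than at 3 h and 2490 (7.73%) higher, with a median log2 ratio of -0.19 (interval -0.20 to -0.18). It was -0.18 (interval -0.29 to -0.09) among whole-number transcripts and 0.01 (interval -0.01 to 0.03) at a mean CPM of 100 or more. At a mean CPM of 10 or more, 1400 were at least 2-fold lower and 232 higher. Under TMM and size factors the treated time ratios rose by 0.18 and 0.19, and the lower transcripts made up 55.8% and 54.9% of those past 2-fold instead of 68.9%; the median changed sign, to 0.0056, with size factors. In TPM the lower transcripts made up 79.2%, with 6257 lower and 1639 higher, and the median was -0.35. The treated and untreated time ratios, which share no library, were nearly unrelated across transcripts (Pearson r 0.05, Spearman rho 0.07). The values were 0.06 and 0.08 at a mean CPM of 10 or more, and 0.14 and 0.10 among whole-number transcripts. The untreated ratios had little spread, 0.54 between the 25th and 75th percentiles against 1.01 with triptolide. A low correlation therefore does not show that the drug removed a change with time.

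Longer transcripts had lower triptolide ratios than shorter ones. At 6 h the median log2 ratio was 0.57 in the 129 transcripts under 200 nt (interval 0.33 to 0.76), 0.04 from 200 to 500 nt, -0.13 from 500 to 1000 nt, -0.12 from 1000 to 2000 nt, -0.25 from 2000 to 4000 nt, -0.37 from 4000 to 8000 nt (interval -0.40 to -0.34) and -0.47 in the 963 transcripts of 8000 nt or more (interval -0.53 to -0.41). The medians of the classes from 500 to 2000 nt change sign when all ratios are raised by 0.22 as under TMM. Differences between classes do not change under a scaling with 1 factor per library. TPM is no such scaling, since it also divides by effective length, and no class medians are given for it. Signs also turned with abundance: at a mean CPM of 10 or more the 6 h medians were 0.41 from 200 to 500 nt, 0.18 from 500 to 1000 nt (interval 0.13 to 0.22), -0.01 from 1000 to 2000 nt (interval -0.04 to 0.02), -0.30 from 2000 to 4000 nt, -0.52 from 4000 to 8000 nt and -0.68 at 8000 nt or more. At 3 h, over all tested transcripts, the medians went from 0.31 under 200 nt to -0.09 from 4000 to 8000 nt and -0.06 at 8000 nt or more. In the untreated 6 h against 3 h comparison no length class of all tested transcripts had a median beyond 0.05 in size; at a mean CPM of 10 or more the median at 8000 nt or more was -0.06, and among whole-number transcripts the class medians were -0.15 under 200 nt, -0.10 from 500 to 1000 nt, -0.15 from 1000 to 2000 nt and -0.18 from 2000 to 4000 nt. Over all tested transcripts the Spearman correlation of length with the 6 h ratio was weak (-0.09, against -0.06 at 3 h and -0.03 for the untreated time ratio), and it was larger in size among abundant transcripts. At 6 h the Spearman correlation of length with the ratio was -0.47 at a mean CPM of 100 or more, -0.32 from 20 to 100 CPM, -0.15 from 5 to 20 CPM and 0.02 from 1 to 5 CPM. In the same order it was -0.30, -0.18, -0.09 and 0.00 at 3 h. In the untreated time comparison it was -0.04, -0.07, -0.05 and -0.02.

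**Figure D3:**
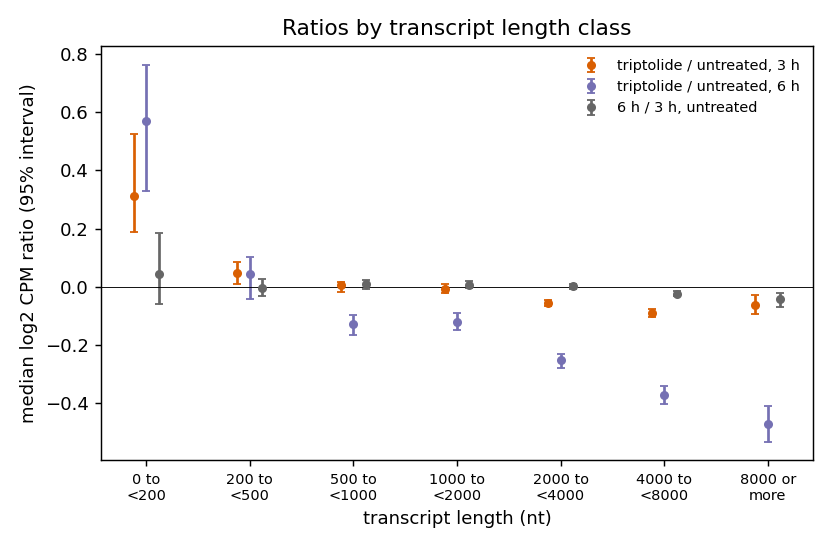
Median log2 CPM ratio (vertical) by class of transcript length in nt (horizontal) for triptolide over untreated at 3 h and 6 h and for untreated 6 h over 3 h, over all tested transcripts; bars are 95% binomial order-statistic intervals over transcripts, not replicate errors. The 6 h triptolide medians go from 0.57 in the shortest class to -0.47 in the longest, and the untreated medians stay within 0.05 of no change.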

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

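The tests of read splitting, of fragment length, of a length bias and of a smaller RNA pool were chosen only after the results they bear on were seen; that of depth was written beforehand. The test of fragment length replaced one written beforehand, the correlation of length with the TPM ratio, which was run and set aside because its outcome was fixed by the direction of the correction.

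The fragments of the treated libraries were longer, as implied by the gap between length and effective length, a column that entered the ratios only through TPM. The implied mean fragment length was 85.9 nt with triptolide and 83.8 nt without at 3 h, a difference of 2.10 nt, and 88.7 nt and 84.8 nt at 6 h, a difference of 3.84 nt. The untreated libraries differed by 0.99 nt from 3 h to 6 h.

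More transcripts were at least 2-fold lower with triptolide at 6 h than at 3 h. Lower depth of the treated 6 h library is argued against, since 7940 transcripts were lower at 6 h and 2620 at 3 h after all libraries had been thinned to one total, and split reads are argued against as the whole cause, since 22.4% of whole-number transcripts were lower at 6 h (interval 17.9% to 27.4%) and 4.73% at 3 h (2.67% to 7.68%). A later position in S phase that both 6 h libraries share is matched in the ratio. A loss of RNA that grows with time in the drug, a drug effect that differs with position in S phase and a difference between single libraries stay open. Tests of further loss were run and set aside because their outcome was fixed by the counts or by the correlation of the 3 h and 6 h ratios. The other 2 were not tested.

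Longer transcripts had lower ratios with triptolide at 6 h. Longer fragments in the treated library change the effective length. That would lower the ratio of transcripts under 200 nt against those of 8000 nt or more by a small amount (a log2 shift of -0.0211). The observed medians differed by 1.04 the other way, so this effect cannot account for the trend. The sign of the shift was fixed by the longer fragments and the observed sign was known, so their disagreement is no test. Other effects of longer fragments were not tested. Splitting of reads is argued against as the whole cause up to 4000 nt. The 85 whole-number transcripts of 2000 to 4000 nt had a median of -0.50 (interval -0.82 to -0.32), and the 61 of 500 to 1000 nt a median of 0.26 (-0.05 to 0.44). Whole-number transcripts were too few to form a class at 4000 nt or more, so splitting stays open there. A length bias of the treated libraries and an effect of the drug on long transcripts cannot be told apart, because the treated 3 h library showed the same sign (-0.0582) and each condition has 1 library.

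Some transcripts were at least 2-fold higher with triptolide at 6 h. Splitting of reads is argued against as the whole cause, since 8.52% of whole-number transcripts were higher (interval 5.69% to 12.2%), against 0.631% in the untreated time comparison (0.0765% to 2.26%). Many of these transcripts were scarce. At a mean CPM of 1 to 2, 13 of 92 whole-number transcripts were higher, and from 10 to 50 CPM, 5 of 91. In the untreated time comparison the same classes held 2 and 0. Shrinking of the RNA pool, which may raise the share of stable transcripts with no new synthesis, cannot be told apart from a true rise because no spike-in values were used here. Over all tested transcripts, the pool would have to be 3.12-fold smaller to place the 95th percentile of the 6 h ratios at no change. That percentile depends on scarce transcripts: 17.2% were at least 2-fold higher at a mean CPM of 1 to 2, against 3.84% at 10 or more. The 1074 transcripts at least 4-fold higher lie above that factor by arithmetic. The factor was taken from these same ratios and does not estimate how far the pool shrank. These 1074 therefore do not bear on whether shrinking accounts for the rises.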

How the results depend on the processing

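The restrictions to whole-number transcripts and to a mean CPM of 10 or more were chosen after the data were seen; the other alternatives were planned. Each condition has 1 library, so no library could be left out. No paired analysis was possible because the groups share only 1 replicate number; an additive fit of treatment and time, which would take their interaction as its only error, was not run. Scaling to ribosomal protein genes, scaling to the total without mitochondrially encoded genes, all alternatives for gene lists and the TPM share of transcript classes were not run, since transcripts were not paired with genes, and TPM was compared per transcript instead of summed per gene. Of 178 values recomputed under an alternative, 66 moved by less than their limit (1.5 times for a count or correlation, the counting or order-statistic interval for other values), 108 moved by more and 4 changed sign where the interval of the value as reported excluded 0. These 4 were median log2 ratios: that of triptolide at 3 h went to 0.0043 with TMM and 0.0050 with size factors, and with size factors that of triptolide at 6 h went to 0.0028 and that of treated 6 h against 3 h to 0.0056, since a scaling shifts all ratios alike. For the same reason the correlation of the 2 triptolide ratios could not change with TMM or size factors, yet it was counted among the 66 under both. In untreated 6 h against 3 h, where more transcripts were higher than lower, more were lower at a limit of 4-fold and among whole-number transcripts. TMM, size factors and thinning kept every count within 1.5 times, and the median triptolide ratio at 6 h went to -0.48 in TPM. In TPM, 2153 transcripts were at least 2-fold higher with triptolide at 6 h and 1639 in the treated time comparison. The median of the treated time comparison also went down in TPM, from -0.19 to -0.35. In both comparisons the fewer higher transcripts thus came with a lower median. What lowered the ratios was not tested. The other settings change the number of transcripts tested or the limit by construction, and in each the lower group stayed the larger with triptolide. In each list that follows, the counts of lower and higher transcripts are given for triptolide at 3 h, triptolide at 6 h, untreated 6 h against 3 h, treated 6 h against 3 h, and the 6 h ratio minus the 3 h ratio. Without a filter on mean CPM they were 7504 and 6066, 14892 and 8285, 5251 and 5871, 10435 and 6993, and 16214 and 12643, and the correlation of the 2 triptolide ratios was 0.27. At a mean CPM of 5 or more they were 666 and 311, 3613 and 861, 186 and 188, 2318 and 507, and 2498 and 632. At a limit of 1.5-fold they were 5839 and 4090, 11892 and 6201, 3502 and 3666, 9964 and 4634, and 10596 and 5510. At 4-fold they were 477 and 255, 2698 and 1074, 201 and 197, 1160 and 471, and 1591 and 831. With counting intervals wholly beyond 2-fold they were 992 and 497, 4707 and 1794, 348 and 399, 2194 and 1098, and 2401 and 1018. They were 15 and 5, 71 and 27, 8 and 2, 42 and 10, and 35 and 12 among whole-number transcripts, with a correlation of 0.77, and 334 and 142, 2322 and 420, 62 and 68, 1400 and 232, and 1481 and 276 at a mean CPM of 10 or more. Depth limits transcripts near 1 CPM, which rest on 19.1 to 27.4 reads per library, and the division of shared reads limits them further.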
